A study of Mus musculus with 9 samples.

How the data were processed

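The series measured gene expression in conventional type 2 dendritic cells (cDC2s) sorted by flow cytometry from mouse bone marrow cultures grown with 100 ng/ml Flt3L for 9 days. There were 3 groups of 3 libraries: wild type (WT), wild type with interferon alpha (IFNa) added on day 5, and cells titled A20iKO (written A20 KO here), labelled as knockout for A20, the ubiquitin-editing enzyme encoded by Tnfaip3, from mice carrying a floxed A20 gene and a CD11c-driven Cre. The group and replicate number of each library came from its title. The treatment protocol field names IFNa on day 5 for all 9 libraries, WT and A20 KO included, so it was not used to assign groups. The titles and a separate treatment entry name IFNa only for the 3 IFNa libraries. Whether the A20 KO cultures were left without IFNa therefore rests on these labels. Per the series' design text, each group came from 3 mice; whether each library holds cells of 1 mouse is not given in the sources used here, and all 9 libraries held both Xist and Y-linked counts.

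RNA was made into libraries with a 3' tag kit, so each read marks the 3' end of a transcript and a level does not depend on transcript length. The deposited values are whole-number counts per gene symbol, 1 column per library, and were not normalized. Per the submitters' processing notes, fastp 0.23.1, Bowtie2, STAR 2.7.10b and featureCounts 2.0.6 were used with the mouse build GRCm39; the role of each tool, the annotation, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Counts of near-identical genes, such as the Bcl2a1, Oas1, Cd209, Klk1b, Iigp1 and H2 families, and of overlapping or antisense genes are therefore uncertain for single members. No genome coordinates are given, since the reference used for gene names and for Y-linked genes is of another build.

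All files listed the same 40879 gene symbols. Total counts ranged from 6900598 to 10552756 per library. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 13251 genes holding 99.83% of the counts. Levels are CPM, each count as a share of its library's total scaled by TMM factors, and errors are the SD of 3 libraries unless stated otherwise. Percent shares of counts, and single-library values of Xist, Ddx3y and stromal transcripts, are shares of the library's total without TMM factors. The common biological coefficient of variation was 0.554. Library pairs within a group differed far beyond sampling noise: the chi-square per degree of freedom, over genes with at least 10 summed counts, was 14.4 in the closest pair. They were thus not repeat reads of 1 library, and each library was counted as 1 replicate. This does not show that libraries of a group hold cells of different mice.

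Differential expression was tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) in 1 fit of all 9 libraries with 6 residual degrees of freedom, for IFNa vs WT, A20 KO vs WT and A20 KO vs IFNa. P-values were adjusted by Benjamini-Hochberg over all genes kept, with a threshold of 0.05. Gene lists, 32 in number, were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01 where at least 5 members were kept, and again with an estimated correlation. The planned test fry asks whether members changed at all, not more than other genes, and was not used for calls. In A20 KO vs WT, lists given below with a camera adjusted p above 0.05 had fry adjusted p of 0.0291 (cDC2), 0.0262 (co-stimulatory), 0.0319 (cell death) and 0.0378 (neutrophil). For the dendritic cell transcription factor and A20 partner lists the fry adjusted p was 0.326 and 0.856. Counts of list members past the threshold are given over all genes and adjusted over the list alone. Lists share members, so results on several lists are not separate lines of evidence. Genes also in another list numbered 21 of 42 in the mature dendritic cell list, 15 of 41 in the NF-kB list and 13 of 42 in the cytokine list. Where a group held no count, a fold is a bound computed against 3 counts over the group; where it held 1 to 3 counts, the ratio is given with its 95% exact interval. Bounds and intervals cover counting error only, since the reads carry no molecular identifiers in the sources used here. Standard errors of log2 fold changes were derived from the F statistic.

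The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names, per comparison, the 8 genes of largest increase and the 8 of largest decrease among those past the threshold with at least 10 CPM in the higher group and no overlap between the groups' libraries, leaving out predicted and identifier-only genes, antigen receptor segments, Y-linked genes and Xist. It adds up to 4 members of each list described, by smallest p, and 10 genes named in any case (Tnfaip3, Irf8, Irf4, Batf3, Id2, Zeb2, Xcr1, Clec9a, Sirpa and Itgam). Genes outside this rule are marked where they appear. Some genes that the rule or a count covers are not reported here.

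The tests were checked on simulated counts made from the levels, depths and dispersions of the 13251 genes. In each comparison 100 genes were changed 2-fold and 100 were changed 4-fold. These were drawn from genes with a mean of at least 10 CPM over all libraries, so recovery at lower levels was not measured. The test recovered 81% of the 4-fold changes for IFNa vs WT, 79% for A20 KO vs WT and 77% for A20 KO vs IFNa. It recovered 22%, 22% and 19% of the 2-fold changes in the same order, so a change of 2-fold or less that did not pass the threshold was often not detectable with 3 libraries per group. The share of calls on unchanged genes was 6.31%, 9.01% and 4.95%.

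The alternatives tried were DESeq2 1.42.0, limma-voom, other scaling factors, other filters on low counts, fits of the 2 groups compared, the replicate number as a block, robust dispersion, stricter thresholds and leaving out each library. A stromal score as covariate, a fit without the 3 libraries richest in stromal transcripts, a fit without the most abundant gene and sample quality weights were added after seeing the data. The responses to IFNa and in A20 KO were compared beside 50 simulations of unchanged groups that share the WT libraries.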

Results

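Expression was measured in 9 libraries of sorted mouse cDC2s, the dendritic cell subset that presents antigen mainly to CD4 T cells, with 3 libraries per group. Every library held both Xist (240 to 872 CPM) and the Y-linked Ddx3y (30.7 to 96.4 CPM), 2 genes chosen after their values were seen. Whether cells of several mice were pooled is not given in the sources used here, so n and SD below refer to libraries. Total counts were 6900598 to 10552756 in WT, 7041519 to 10246810 with IFNa and 7187359 to 9518822 in A20 KO. All levels below are mean CPM ± SD over n = 3 libraries. Collagen and other stromal transcripts differed between libraries of the same group. Col1a1, chosen after its values were seen, stood at 2979 CPM in WT replicate 2, 2968 in IFNa replicate 3 and 2880 in A20 KO replicate 1, against 285 to 1466 CPM in the other libraries. The long noncoding Gm26917, chosen here after its values were seen because it held more counts than any other gene, took 7.41% ± 3.5 of counts in WT, 14.7% ± 2.53 with IFNa and 13.1% ± 0.799 in A20 KO. Mitochondrial genes took 3.82% ± 0.407, 2.84% ± 0.165 and 3.61% ± 0.0461 of counts in the same order, and the bearing of this share on the calls was not tested.

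Tnfaip3, the gene that encodes A20, was read in every library. It held 232, 51 and 42 counts in the WT libraries, 73, 84 and 74 with IFNa, and 285, 476 and 377 in the libraries titled A20iKO, written A20 KO here. Its level was 11.3 ± 10 CPM in WT, 9.56 ± 1.53 with IFNa and 43.7 ± 8.98 in A20 KO, a rise over WT of 1.95 on the log2 scale (SE 0.515; edgeR Benjamini-Hochberg adjusted p = 0.028). The deleted exons are not given in the sources used here and a 3' tag outside them checks nothing about the deletion. By edgeR, the rise no longer passed the threshold without WT replicate 2 or 3 or A20 KO replicate 2 or 3, where the log2 fold change was 1.69, 1.55, 1.77 and 2.01 and the adjusted p 0.0718, 0.0776, 0.113 and 0.0645. Without WT replicate 1 it was 2.99.

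**Figure D1:**
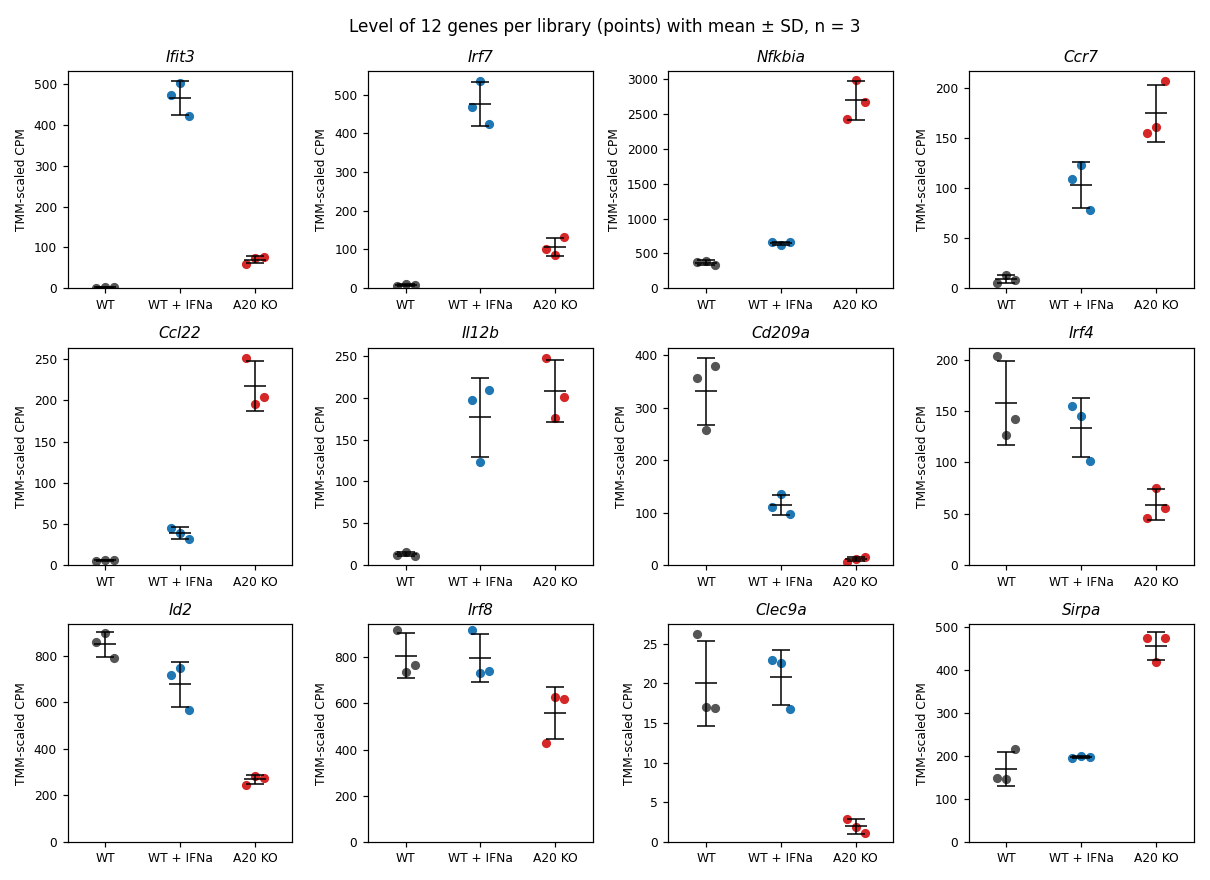
Level of 12 genes in each library (points; TMM-scaled CPM, linear axes from 0) in WT, IFNa-treated WT and A20 KO, with bars for the mean ± SD of 3 libraries. Ifit3 and Irf7 stood highest with IFNa, Nfkbia and Ccl22 in A20 KO, and Cd209a, Irf4 and Id2 lowest in A20 KO.

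The first comparison sets cDC2s sorted from WT cultures given IFNa against cDC2s sorted from WT cultures. IFNa was added during culture, before the sort. A response of cDC2s was therefore not separated from a change in which cells grew or were sorted, which was not tested. Interferon-stimulated genes rose. Ifit3, which encodes an antiviral RNA-binding protein, rose from 1.59 ± 1.09 to 466 ± 41.3 CPM, Ifi44 from 1.12 ± 0.665 to 473 ± 35, and Ifi213 from 1.84 ± 1.73 to 375 ± 73.6. Of the 52 type I interferon-stimulated genes tested, 51 rose and 1, Ifitm1, fell (104 ± 12.1 to 49.8 ± 6.61 CPM), and the counts adjusted over the list alone were also 51 and 1. The median log2 fold change of the list was 3.3. For the interferon list, the camera adjusted p was 3.87e-94, and adjusted p = 0.0058 with an estimated correlation.

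The genes of largest increase also included Oas1b, an oligoadenylate synthetase family member with no count in WT and 22.9 ± 8.04 CPM with IFNa, at least 210-fold higher. Iigp1c rose 734-fold (counting interval 217 to 6480), Oasl1 445-fold (191 to 2720) and Slfn1 660-fold (111 to 24500), each over 1 to 3 counts in WT. Iigp1, an immunity-related GTPase, rose from 0.412 ± 0.289 to 78.8 ± 27 CPM. Of 22 tested guanylate-binding and immunity-related GTPases and other interferon-gamma-type genes, 11 rose, or 18 adjusted over the list alone, among them Ifi47, Igtp and the transcription factor Irf1 (88 ± 4.78 to 251 ± 18 CPM). For the gamma-type list, the camera adjusted p was 7.84e-17, and adjusted p = 0.0072 with an estimated correlation.

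Antigen presentation genes moved in opposite directions. Of 23 MHC class I presentation genes, 13 rose and none fell, or 16 adjusted over the list alone. They included the light chain B2m (2766 ± 74.6 to 7881 ± 761 CPM), H2-K1 (676 ± 56.4 to 2345 ± 181 CPM) and the transactivator Nlrc5. For the class I list, the camera adjusted p was 1.54e-19, and adjusted p = 0.041 with an estimated correlation. Of 20 class II genes, 6 fell and 1 rose, or 8 and 3 adjusted over the list alone. H2-Ab1 fell from 8502 ± 1120 to 5392 ± 376 CPM and H2-Ob from 213 ± 24.7 to 93.6 ± 6.46 CPM. The class II call (camera adjusted p = 0.00347) was lost at adjusted p = 0.4 with an estimated correlation.

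Genes of the mature, migratory dendritic cell programme rose with IFNa, 15 of 41 over all genes and 23 adjusted over the list alone, with none lower. For the mature cell list, the camera adjusted p was 1.56e-17, and adjusted p = 0.0058 with an estimated correlation. Ccr7, the lymph node homing receptor, rose from 9.04 ± 4.06 to 104 ± 22.8 CPM and Il12b, the IL-12 p40 subunit, from 12.9 ± 2.75 to 177 ± 46.8 CPM. Among 26 cytokines and chemokines, 7 rose and none fell, or 10 adjusted over the list alone, with Ccl5 at 46.3 ± 7.86 and 239 ± 32.2 CPM. For the cytokine list, the camera adjusted p was 4.42e-06, and adjusted p = 0.012 with an estimated correlation. The proliferation list rose, with 8 of 36 members higher and 16 adjusted over the list alone, such as Birc5, but its camera adjusted p of 3.75e-11 became an adjusted p = 0.24 with an estimated correlation. Of 17 neutrophil and granulocyte precursor markers, 3 rose over all genes and 3 adjusted over the list alone: S100a8 (36.5 ± 3.96 to 121 ± 8.54 CPM), S100a9 (47.8 ± 0.173 to 157 ± 18.5 CPM) and Prtn3. For the neutrophil list, the camera adjusted p was 1.83e-05, and adjusted p = 0.042 with an estimated correlation.

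Fewer genes fell. The lectin gene Cd209e had 21.4 ± 5.54 CPM in WT and no count with IFNa, at least 175-fold lower, and its relative Cd209d fell from 140 ± 13.5 to 9.63 ± 3.42 CPM. Fcgr2b, the inhibitory Fc receptor, fell from 83.7 ± 16.5 to 13.7 ± 3.75 CPM and Trf, which encodes transferrin, from 305 ± 23.5 to 58.2 ± 11.4 CPM. Cox6b2, Dapk1, Dgka and Sema6d were the other genes of largest decrease. By edgeR with Benjamini-Hochberg adjustment, the call was lost for Cox6b2 without WT replicate 3 or IFNa replicate 3 (adjusted p = 0.0611 and 0.0565), for Dgka without IFNa replicate 1, 2 or 3 (0.0808, 0.0629 and 0.0565), and for Sema6d without WT replicate 1 or IFNa replicate 1, 2 or 3 (0.103, 0.11, 0.0914 and 0.0669).

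Of 24 cholesterol synthesis genes, 4 fell, among them Mvd, Msmo1 and Cyp51, or 10 adjusted over the list alone. For the cholesterol list, the camera adjusted p was 3.17e-08, and adjusted p = 0.14 with an estimated correlation. In the cDC1 identity list of 28 genes, 3 fell and 1 rose, or 6 and 1 adjusted over the list alone. Naaa, Septin3 and Cadm1 fell. Each of these 6 named genes lost its call when single libraries were left out, and the largest edgeR Benjamini-Hochberg adjusted p was 0.0579 for Mvd, 0.0964 for Msmo1, 0.192 for Cyp51, 0.106 for Naaa, 0.0848 for Septin3 and 0.209 for Cadm1. These came without IFNa replicate 1 for Mvd, Msmo1 and Cadm1 and without IFNa replicate 2 for the others. Cadm1 also did not pass with the other scaling factors tried (0.0512 to 0.0596). The call on that list (camera adjusted p = 0.00426) was lost at adjusted p = 0.24 with an estimated correlation and at 0.108 without WT replicate 1.

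In all, 318 genes rose and 93 fell with IFNa among 13251 tested (edgeR, Benjamini-Hochberg adjusted p under the threshold of 0.05). All 411 had no overlap between the groups' libraries, as did 18.2% of all genes, where chance gives 10%. A call with 3 libraries against 3 rarely arises without such separation, so its share among called genes is no separate support for the calls. Of the genes named in any case, none of Irf8 (807 ± 97.6 and 798 ± 105 CPM), Irf4 (158 ± 40.9 and 134 ± 28.6), Id2 (849 ± 52.8 and 678 ± 96.4), Batf3, Zeb2, Xcr1, Clec9a, Sirpa (170 ± 39.6 and 198 ± 2.34) or Itgam passed the test. The count of genes that fell was 45, 47, 58, 43 and 48 without WT replicate 1, WT replicate 3 and IFNa replicates 1, 2 and 3 in turn. Scaling by library size alone gave 286 higher and 184 lower, so the share of higher calls went from 77.4% to 60.9%, with a shift of the median log2 fold change of all genes to -0.15.

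The second comparison asks how cDC2s labelled as A20 KO differ from WT; the loss of A20 was not checked by these data. A20 limits NF-kB signalling, and NF-kB target genes were higher in A20 KO. Nfkbia, the NF-kB inhibitor gene, rose from 367 ± 31.3 to 2697 ± 281 CPM, Traf1 from 12.4 ± 1.11 to 115 ± 16.1, Marcksl1 from 22 ± 3.29 to 179 ± 33.9 and Relb, an NF-kB subunit, from 37.6 ± 15.1 to 322 ± 6.57 CPM. Of 41 NF-kB target genes, 21 rose and 1 fell, or 26 and 1 adjusted over the list alone. For the NF-kB list, the camera adjusted p was 5.63e-14, and adjusted p = 0.032 with an estimated correlation.

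The mature dendritic cell programme rose, with 24 of 41 members higher and none lower, or 32 adjusted over the list alone, at a median log2 fold change of 3.09. For the mature cell list, the camera adjusted p was 1.89e-26, and adjusted p = 0.0033 with an estimated correlation. Ccr7 rose from 9.04 ± 4.06 to 175 ± 28.4 CPM, Ccl22, a chemokine that attracts regulatory T cells, from 5.73 ± 0.602 to 217 ± 30.2, and Il12b from 12.9 ± 2.75 to 208 ± 37 CPM. Traf1, Marcksl1 and Relb, named above for NF-kB, are also members of the mature cell list. Ccl22 and Il12b are also members of the cytokine list. Of 26 cytokines and chemokines, 11 rose and none fell, or 15 adjusted over the list alone, with Ltb and Ccl5 among them. For the cytokine list, the camera adjusted p was 1.17e-08, and adjusted p = 0.0085 with an estimated correlation. Cd274, which encodes PD-L1, rose from 11.5 ± 5.18 to 136 ± 9.26 CPM and Nectin2 from 0.287 ± 0.195 to 43.6 ± 2.01 CPM. The co-stimulatory and checkpoint list as a whole, with 7 higher and 5 lower of 22, or 10 and 5 adjusted over the list alone, did not pass (camera adjusted p = 0.0903).

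Interferon-stimulated genes rose in A20 KO libraries, whose titles name no IFNa, although the protocol field names it for all libraries: 42 of 52 were higher and none lower, or 46 adjusted over the list alone, at a median log2 fold change of 2.13. For the interferon list, the camera adjusted p was 5.66e-33, and adjusted p = 0.032 with an estimated correlation. Ly6a rose from 38.4 ± 9.07 to 648 ± 104 CPM, Ifi44 from 1.12 ± 0.665 to 70.6 ± 22, Rsad2 from 6.22 ± 1.87 to 66.1 ± 4 and Ifi27l2a from 52.7 ± 9.84 to 371 ± 32.9 CPM. Of 22 interferon-gamma-type genes, 11 rose and 1 fell, or 14 and 1 adjusted over the list alone, including Gbp5 (0.558 ± 0.797 to 37.8 ± 9.29 CPM). For the gamma-type list, the camera adjusted p was 4.11e-07, and adjusted p = 0.032 with an estimated correlation. B2m and H2-K1 rose, with 9 of 23 class I genes higher and 12 adjusted over the list alone. For the class I list, the camera adjusted p was 3.89e-07, and adjusted p = 0.14 with an estimated correlation. Class II genes split, with 9 of 20 lower and 4 higher, or 10 and 5 adjusted over the list alone. H2-Aa fell from 11867 ± 1724 to 4554 ± 46.1 CPM, while H2-Eb2 and the lysosomal thiol reductase gene Ifi30 rose. For the class II list, the camera adjusted p was 0.00186, and adjusted p = 0.32 with an estimated correlation.

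The cDC1 identity list, genes of the subset that cross-presents antigen, fell: 14 of 28 were lower and 1 higher, or 17 and 2 adjusted over the list alone, at a median log2 fold change of -1.15. For the cDC1 list, the camera adjusted p was 1.13e-09, and adjusted p = 0.032 with an estimated correlation. Clec9a, a receptor for dead cells, fell from 20 ± 5.35 to 1.96 ± 0.919 CPM, Naaa from 213 ± 27.9 to 21 ± 1.79, Rab7b from 191 ± 24.9 to 55.7 ± 3.95 and the transcriptional regulator Id2 from 849 ± 52.8 to 269 ± 20.8 CPM. Xcr1 had 8.64 ± 4.5 and 1.21 ± 1.71 CPM and did not pass the test (edgeR Benjamini-Hochberg adjusted p = 0.125), nor did Batf3. Irf8, which drives cDC1 development, had 807 ± 97.6 CPM in WT and 559 ± 113 in A20 KO (log2 fold change -0.53, SE 0.167) and lay just above the threshold (edgeR Benjamini-Hochberg adjusted p = 0.0645). Over 23 alternatives its edgeR, DESeq2 or limma adjusted p ran from 0.000469 to 0.194 and was past the threshold in 8. Of these 8, the lowest came with the stromal covariate and another with sample quality weights (limma adjusted p = 0.0472). Both settings were added after seeing the data. Among settings fixed before, the lowest was 0.0105 with DESeq2. With single libraries left out, the edgeR adjusted p ran from 0.0534 to 0.194, so Irf8 passed in none of these fits. Xcr1 passed without A20 KO replicate 3 (edgeR Benjamini-Hochberg adjusted p = 0.0181).

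Genes of cDC2s themselves went both ways, 13 of 35 higher and 10 lower, or 17 and 11 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0793). Sirpa, a cDC2 surface marker, rose from 170 ± 39.6 to 456 ± 32.5 CPM, Csf1r, the M-CSF receptor gene, from 146 ± 9.99 to 594 ± 38.9 and Clec7a, which encodes Dectin-1, from 15.9 ± 5.32 to 143 ± 25.7 CPM. Cd209a, the mouse gene for DC-SIGN, fell from 331 ± 64.1 to 11 ± 4.33 CPM, Clec10a from 516 ± 129 to 104 ± 7.8, and Itgam from 239 ± 65.7 to 130 ± 9.1 CPM. Itgam lost its call without WT replicate 3 or A20 KO replicate 2 (edgeR Benjamini-Hochberg adjusted p = 0.0658 and 0.063). Among dendritic cell transcription factors, 5 of 35 rose and 9 fell, or 10 and 13 adjusted over the list alone. Irf4, needed for cDC2 development, fell from 158 ± 40.9 to 58.7 ± 15 CPM, Irf5 from 408 ± 121 to 141 ± 18 and Klf4 from 586 ± 67.2 to 227 ± 10.1 CPM (camera adjusted p = 0.375 for the list, whose median and mean lay above 0 while the test pointed down). Zeb2 did not pass.

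Of 32 monocyte and macrophage markers, 17 rose and 1 fell, or 21 and 2 adjusted over the list alone. The levels in WT and A20 KO were, for Gpnmb, 19.5 ± 11 and 231 ± 18.1 CPM, for Apoe 44.8 ± 10.2 and 208 ± 23.9 and for Mertk, a receptor for apoptotic cells, 0.442 ± 0.209 and 22.3 ± 3.53 CPM. For the monocyte list, the camera adjusted p was 5.09e-10, and adjusted p = 0.022 with an estimated correlation. With IFNa against WT, 5 of the 32 rose and 2 fell, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0562). Apoe, 1 of those that rose, stood at 199 ± 36.1 CPM with IFNa. Of 13 haematopoietic progenitor markers, 7 rose, or 11 adjusted over the list alone, including Kit (23.1 ± 1.36 to 71 ± 12.8 CPM) and Sox4. The 2 members of smallest p, Ly6a and Ifitm1, are also in the interferon list, and the progenitor list was not tested without them. For the progenitor list, the camera adjusted p was 7.03e-09, and adjusted p = 0.0085 with an estimated correlation. In the neutrophil list, the granule protein genes Prtn3 and Mmp8 rose, Prtn3 from 0.594 ± 0.545 to 175 ± 39 CPM and Mmp8 from 8.6 ± 3.54 to 77.8 ± 16.5 CPM. By contrast, S100a8 fell from 36.5 ± 3.96 to 5.99 ± 2.02 and S100a9 from 47.8 ± 0.173 to 4.85 ± 1.46 CPM (5 of 17 list members higher and 2 lower, or 5 and 3 adjusted over the list alone; camera adjusted p = 0.24). Ly6c2, shared by monocytes and plasmacytoid dendritic cells, rose from 26 ± 10.7 to 741 ± 115 CPM and Siglech fell from 242 ± 29.4 to 63 ± 13.6 CPM. The rise of Ly6c2 was not particular to A20 KO, since it also stood at 679 ± 103 CPM in IFNa-treated WT (edgeR Benjamini-Hochberg adjusted p = 4.74e-07 against WT). The plasmacytoid list, 9 of 26 higher and 4 lower, or 10 and 5 adjusted over the list alone, passed with the preset correlation (camera adjusted p = 0.0282) and not with the estimated one (adjusted p = 0.28 with an estimated correlation). The camera adjusted p of the plasmacytoid list was 0.0533, 0.0762, 0.0509 and 0.0741 without WT replicate 1, WT replicate 3, A20 KO replicate 2 and A20 KO replicate 3.

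The proliferation list rose in A20 KO, with 26 of 36 members higher and 1 lower, or 33 and 1 adjusted over the list alone. Birc5 rose from 72.1 ± 7.98 to 236 ± 7.01 CPM and Top2a from 441 ± 53.2 to 909 ± 60.1 CPM. For the proliferation list, the camera adjusted p was 5.9e-20, and adjusted p = 0.068 with an estimated correlation. Immediate-early and stress genes fell, 12 of 29 lower and 1 higher, or 13 and 2 adjusted over the list alone, with Fos, Ier2, Ier5 and Zfp36 lowest in p. For the immediate-early list, the camera adjusted p was 2.71e-06, and adjusted p = 0.12 with an estimated correlation. The genes of largest increase were Acod1, which encodes the itaconate-producing enzyme, and Bcl2a1a, Tm4sf5, Pglyrp2, Gem and Mlkl, all with no count in WT and at least 402-, 273-, 162-, 109-, 93.2- and 92.7-fold higher in that order. They also included Fpr2 (0.156 ± 0.0968 to 121 ± 7.01 CPM) and Bcl2a1d (495-fold over few counts, counting interval 109 to 24000). Largest decreases were in Klk1b11 and Cd209e, with no count in A20 KO and at least 227- and 185-fold lower. Others were in Tlr11 (ratio 0.00327, counting interval 6.93e-05 to 0.0154), and in F2rl2, Cd209d, Cd209a, Alox5 (122 ± 1.99 to 4.65 ± 2.64 CPM) and Skint3.

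In all, 765 genes rose and 651 fell in A20 KO against WT (edgeR, Benjamini-Hochberg). Of these 1416 genes, 99.6% had no overlap between the groups' libraries, which the selection of called genes nearly brings by itself. Among all genes the share was 28%, where chance gives 10%. Without A20 KO replicate 2 or 3 the count of genes that rose was 480 and 478.

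**Figure D2:**
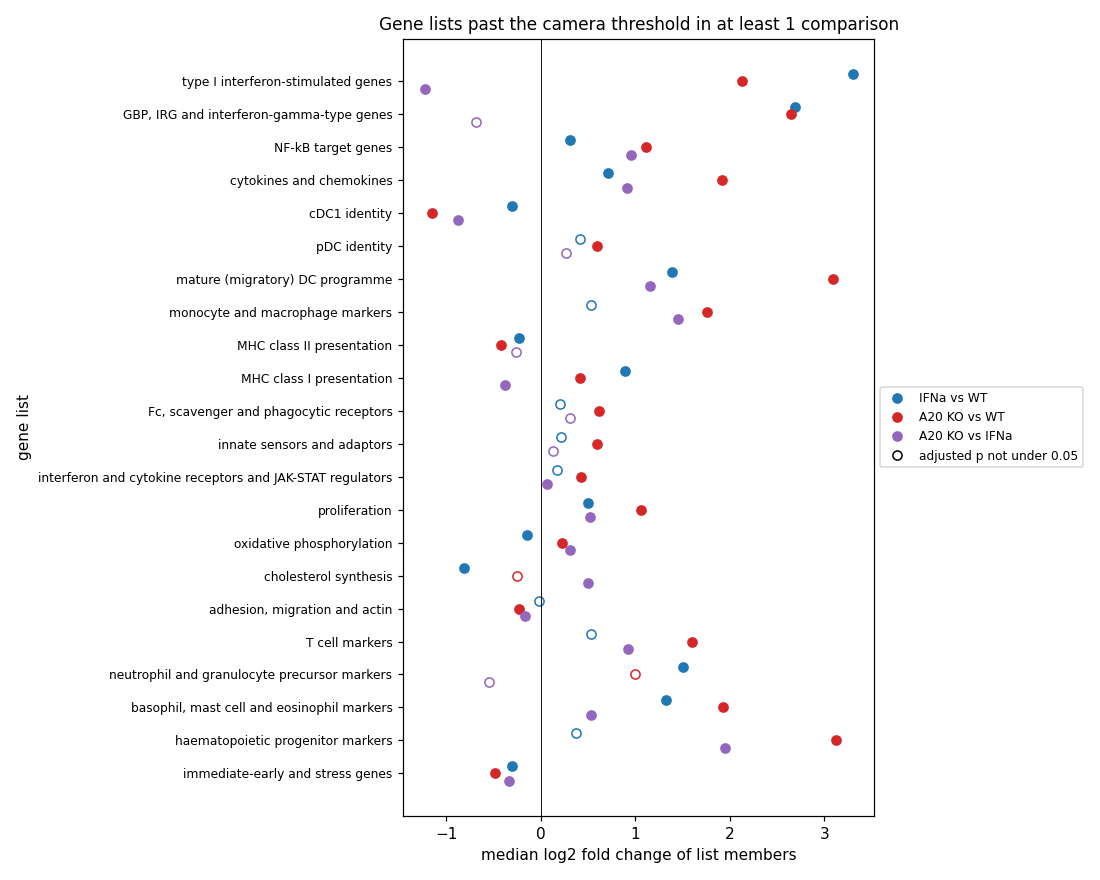
Median log2 fold change (x axis) of the members of each gene list (y axis) that passed the camera threshold in at least 1 of 3 comparisons, coloured by comparison; filled points passed with the preset correlation and open points did not. The interferon list had medians of 3.3 with IFNa and 2.13 in A20 KO against WT, and the cDC1 list of -1.15 in A20 KO.

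The third comparison sets A20 KO cDC2s against IFNa-treated WT cDC2s and so tests where both states differ. Interferon-stimulated genes were lower in A20 KO: 29 of 52 fell and 1 rose, or 41 and 1 adjusted over the list alone. For the interferon list, the camera adjusted p was 6.51e-47, and adjusted p = 0.024 with an estimated correlation. Rsad2 stood at 309 ± 13.2 CPM with IFNa and 66.1 ± 4 in A20 KO, Ifit2 at 214 ± 54.6 and 37.5 ± 1.93, and Ifitm1 moved the other way, at 49.8 ± 6.61 and 326 ± 36.9 CPM. NF-kB target genes were higher in A20 KO, with 16 of 41 up and 1 down, or 21 and 1 adjusted over the list alone. Nfkbia stood at 647 ± 22.2 and 2697 ± 281 CPM, Icam1 at 25.9 ± 2.23 and 135 ± 6.58 and Ehd1 at 28.6 ± 2.62 and 117 ± 3.15 CPM. For the NF-kB list, the camera adjusted p was 1.1e-16, and adjusted p = 0.029 with an estimated correlation.

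The mature dendritic cell list was also higher in A20 KO than with IFNa, 12 of 41 up and none down, or 20 adjusted over the list alone. Ccl22 stood at 38.9 ± 6.75 and 217 ± 30.2 CPM and Tbc1d4 at 53.8 ± 7.36 and 372 ± 51.2 CPM. For the mature cell list, the camera adjusted p was 3.04e-20, and adjusted p = 0.0075 with an estimated correlation. Of 26 cytokines and chemokines, 6 rose and 1 fell, or 8 and 2 adjusted over the list alone. Cxcl2, a neutrophil attractant, stood at 9.35 ± 1.14 and 104 ± 9.68 CPM. For the cytokine list, the camera adjusted p was 0.000184, and adjusted p = 0.026 with an estimated correlation. Monocyte and macrophage markers were higher, 9 of 32 up and 1 down, or 17 and 2 adjusted over the list alone. Lyz2 stood at 129 ± 17.6 and 699 ± 88.7 CPM and Cd14 at 9.18 ± 2.32 and 71.7 ± 11.9 CPM. For the monocyte list, the camera adjusted p was 3.33e-09, and adjusted p = 0.026 with an estimated correlation. Progenitor markers were higher, 4 of 13 up, Ifitm1 among them, and 1, Ly6a, down, or 9 and 1 adjusted over the list alone. For the progenitor list, the camera adjusted p was 2.92e-06, and adjusted p = 0.024 with an estimated correlation. The cDC1 list was lower, 10 of 28 down and none up, or 13 and 2 adjusted over the list alone, with Naaa at 125 ± 11.6 and 21 ± 1.79 CPM. For the cDC1 list, the camera adjusted p was 7.89e-07, and adjusted p = 0.1 with an estimated correlation. Of 47 oxidative phosphorylation genes, 3 were higher in A20 KO and none lower, also when adjusted over the list alone, at a median log2 fold change of 0.307. The camera adjusted p of this list was 7.8e-08, and 0.042 with an estimated correlation.

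Among single genes, Hp, which encodes haptoglobin, stood at 3.21 ± 0.338 CPM with IFNa and 232 ± 28.8 in A20 KO, and Cp, the ceruloplasmin gene, at 2.62 ± 1.86 and 130 ± 20 CPM. Dll4, a Notch ligand, had no count with IFNa and 11.1 ± 1.87 CPM in A20 KO, at least 90.9-fold higher. Dnase1l3, Pilra, Susd2, Cd38 and F10 completed the largest increases. Klk1b11 and Klk15 had no count in A20 KO and were at least 588- and 106-fold lower. S100a9 stood at 157 ± 18.5 and 4.85 ± 1.46 CPM, and Ifit1bl1, F2rl2, Ngp, Skint3 and S100a8 completed the largest decreases. Irf4 (134 ± 28.6 and 58.7 ± 15 CPM), Id2 and Clec9a were lower and Sirpa higher in A20 KO. By the same test Irf8 (798 ± 105 and 559 ± 113 CPM; edgeR Benjamini-Hochberg adjusted p = 0.11), Batf3, Zeb2, Xcr1 and Itgam did not pass. The call was lost for Susd2 without IFNa replicate 1 or 3 or A20 KO replicate 2 or 3 (edgeR Benjamini-Hochberg adjusted p = 0.0722, 0.0632, 0.137 and 0.0816), for Cd38 without IFNa replicate 2 or A20 KO replicate 2 (0.0666 and 0.0953) and for F10 without IFNa replicate 2 (0.0538). It was lost for Klk15 without IFNa replicate 1 or 2 or A20 KO replicate 2 or 3 (0.0886, 0.0583, 0.0585 and 0.0592), and for Irf4 without IFNa replicate 1 or 2 or A20 KO replicate 3 (0.0631, 0.0531 and 0.0594). Xcr1 passed without A20 KO replicate 3 (0.0341) and Itgam without WT replicate 2 (0.0203).

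In all, 271 genes were higher and 452 lower in A20 KO than with IFNa. The higher count was 173, 167, 145 and 147 and the lower count 227, 273, 276 and 303 without IFNa replicate 1, IFNa replicate 2, A20 KO replicate 2 and A20 KO replicate 3. Scaling by library size alone took the share of higher calls from 37.5% to 49.4% and the median of all genes to 0.12.

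The responses to IFNa and in A20 KO overlapped. Of 318 genes higher with IFNa and 765 higher in A20 KO, 248 were higher in both, against 18.4 expected of independent lists and 0.02 on average in 50 simulations of unchanged groups sharing the WT libraries. For genes lower in both, the count was 62, against 4.57 and 0. Unchanged groups give almost no calls, so these simulated counts say nothing about overlap that shared controls bring among called genes. The count of genes lower in both was 25, 28, 27, 29 and 40 without WT replicate 1, WT replicate 3, IFNa replicate 2, IFNa replicate 3 and A20 KO replicate 2. Over all genes the log2 fold changes had a Pearson r of 0.657, where the simulations gave 0.499, and a covariance of 1.19, where they gave 0.308. The simulations set every group at WT levels and filtered low counts anew. Genes with almost no WT counts therefore fell out of the simulations but not of the observed values. The differences between observed and simulated values mix this change of genes with any shared response. The jackknife SE over libraries was 0.197 for r and 1.01 for the covariance, beside excesses of 0.158 and 0.886. It was 71.4 for the genes higher in both and 44.1 for those lower in both. The fits with 1 library left out kept 13925 to 14203 genes, and the simulations were not run for them. These SEs therefore mix sampling error with a change of genes and of the shared-control value, and the error of the excesses is not known. Without WT replicate 1, 2 or 3 the covariance was 2.07, 2.52 and 2.05, and with a strict filter on low counts it was 0.617. The WT libraries cannot be divided into parts of 2 or more, so part of the excess of shared genes over independent lists may come from the shared controls. Of the 248 genes higher in both, 49 were lower in A20 KO than with IFNa and 36 higher.

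Genes called in opposite directions numbered 11 and were chosen after their values were seen. With IFNa, 5 rose that fell in A20 KO: they included S100a8, S100a9, Ifi205 and Klrk1, which encodes the receptor NKG2D. The other 6 fell with IFNa and rose in A20 KO: Lyz2 (WT, IFNa and A20 KO at 364 ± 48.2, 129 ± 17.6 and 699 ± 88.7 CPM), Anpep, Ifitm1, Tmem176a, Tmem176b and H2-DMb2.

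**Figure D3:**
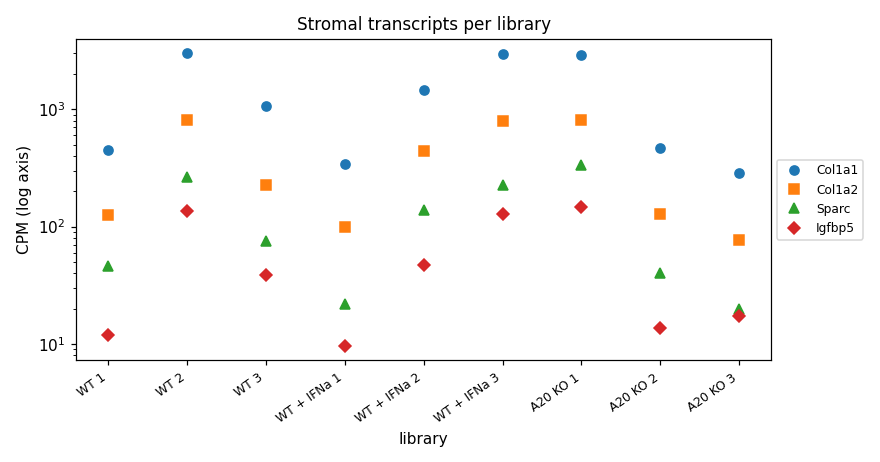
Level of 4 stromal transcripts, chosen after their values were seen (CPM without TMM factors, log axis) in each of the 9 libraries. Col1a1 stood at 2979, 2968 and 2880 CPM in WT replicate 2, IFNa replicate 3 and A20 KO replicate 1, above the 285 to 1466 CPM of the others, with 1 such library in each group.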

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

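The stromal covariate, the fit of the 6 libraries poorer in stromal transcripts, the removal of Gm26917 and the sample quality weights were chosen after seeing the data; the other alternatives were planned. No named gene or list called in a comparison changed direction under any alternative run. Over genes and settings, 6778 values kept their side of the threshold, 268 lost the call and 140 gained it; for lists these counts were 980, 56 and 17. With DESeq2, 494 genes were higher and 211 lower with IFNa, 497 were higher in A20 KO than with IFNa, and 127 were lower in both. Library size alone gave 184 lower with IFNa. Without a filter on low counts, 164 were lower with IFNa and 430 higher in A20 KO than with IFNa. In fits of only the 2 groups compared, 469 were higher in A20 KO than with IFNa and Tnfaip3 rose by 1.92 (edgeR adjusted p = 0.0614). At an adjusted p under 0.01, 188 genes were higher and 31 lower with IFNa, 426 and 348 in A20 KO, and 134 and 213 in A20 KO against IFNa. With a log2 fold change of at least 1, the lower counts were 46, 396 and 296. The stromal covariate gave 517 higher and 237 lower with IFNa, 1002 lower in A20 KO, and 470 and 801 in A20 KO against IFNa. Quality weights gave 566 higher in A20 KO than with IFNa, and the 6 libraries poorer in stromal transcripts a Tnfaip3 rise of 1.79 (edgeR adjusted p = 0.117). Of the 50 list calls, 21 held with an estimated correlation. The cause of these changes was not tested, except that stricter thresholds call fewer genes by construction. With the replicate number as a block, 253 genes were higher and 45 lower with IFNa, and 589 and 486 in A20 KO. In A20 KO against IFNa the block gave 200 and 335, and 29 genes were lower in both responses. Whether libraries of equal number share a mouse or a day is not given in the sources used here. Their deviations from the group means correlated between -0.37 and 0.237. The stromal-rich IFNa replicate 3 and A20 KO replicate 1, of unequal number, reached 0.358, so these correlations cannot decide on a pairing. Leaving out 1 library gave 225 to 319 higher and 43 to 107 lower with IFNa, 478 to 750 higher and 439 to 683 lower in A20 KO, and 145 to 352 higher and 227 to 523 lower in A20 KO against IFNa. It gave 46 to 53 lists, 173 to 242 genes higher and 25 to 68 lower in both, a covariance of 1.45 to 2.52, an r of 0.528 to 0.735 and a Tnfaip3 log2 fold change of 1.55 to 2.99. The strict filter on low counts took the covariance from 1.19 down to 0.617. With 3 libraries per group, changes of 2-fold were recovered in 19% to 22% of simulated genes with a mean of at least 10 CPM. This limits what the depth and number of libraries can show.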

Other observations

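The stromal ratio and depth tests, the bound on mixing, the cDC1 and abundant-marker tests, the stromal covariate and Kdr, named for its values, were chosen after the results were seen.

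Cytokine receptor and JAK-STAT genes changed in A20 KO against WT, 10 of 34 higher and 6 lower, or 15 and 7 adjusted over the list alone. Jak2, a kinase of cytokine receptors, rose from 107.8 ± 11 to 281 ± 28.3 CPM and Il21r from 24.4 ± 2.99 to 117 ± 23.6 CPM (camera adjusted p = 0.006; adjusted p = 0.28 with an estimated correlation). In Fc, scavenger and phagocytic receptors, 8 of 35 rose and 3 fell, or 10 and 3 adjusted over the list alone; Clec4n rose and Cd93 fell from 757 ± 181 to 246 ± 33.1 CPM (camera adjusted p = 0.00823; adjusted p = 0.054 with an estimated correlation). Adhesion and migration genes fell more often than they rose, 12 against 6 of 41, or 16 and 8 adjusted over the list alone; Itgb7 fell from 625 ± 83 to 220 ± 11.2 CPM and Lsp1 from 1795 ± 279 to 649 ± 84.4 CPM (camera adjusted p = 0.0172; adjusted p = 0.28 with an estimated correlation, and 0.0555 and 0.0516 without WT replicate 1 and A20 KO replicate 1). Of 10 basophil, mast cell and eosinophil markers, 4 rose, or 5 adjusted over the list alone, with Mcpt8 at 10.9 ± 4.24 and 53.3 ± 0.615 CPM. The camera adjusted p of this list was 2.54e-05, and 0.068 with an estimated correlation. With IFNa against WT, 2 of the 10 rose and none fell, or 3 and none adjusted over the list alone, with Mcpt8 at 37.3 ± 10.2 CPM. There the camera adjusted p was 0.000827, and 0.17 with an estimated correlation. In A20 KO against IFNa none of the 10 was called, although the list passed (camera adjusted p = 0.00574, and 0.2 with an estimated correlation). Of 9 T cell markers, 2 rose in A20 KO against WT, or 3 adjusted over the list alone. The camera adjusted p was 0.0172, and 0.094 with an estimated correlation and 0.0785 in the 6 libraries poorer in stromal transcripts.

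Cell death genes did not pass as a list in A20 KO (camera adjusted p = 0.152), with 5 of 32 higher and 1 lower, or 8 and 2 adjusted over the list alone; Tnfrsf1b, which encodes TNF receptor 2, rose from 66.9 ± 12.8 to 238 ± 12.1 CPM and Ninj1 from 14.4 ± 2.64 to 72.1 ± 5.79 CPM. Of 32 A20 partners and ubiquitin-editing genes, 2 rose and 1 fell, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.789), and Tnip1, which encodes a protein that binds A20, rose from 44.4 ± 12.7 to 168 ± 31.5 CPM. With IFNa, 7 of 41 NF-kB target genes rose, or 11 adjusted over the list alone, with Relb at 37.6 ± 15.1 and 99.1 ± 5.12 CPM (camera adjusted p = 0.00426; adjusted p = 0.35 with an estimated correlation, and 0.07 without WT replicate 3). Kdr, an endothelial receptor gene, rose from 11.3 ± 8.75 to 179 ± 23.4 CPM with IFNa and to 135 ± 18.5 CPM in A20 KO, and no other member of the stromal list passed the threshold in either comparison.

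Type I interferon-stimulated genes were higher in A20 KO, whose titles name no IFNa while the protocol field names it for all libraries. Mixing of IFNa material into the A20 KO libraries would bring 1 common fraction of each rise; over 51 genes that fraction had a median of 32.5%, and its 90th to 10th percentile ratio of 3.8 stayed short of the bound of 4 set beforehand, so that test left mixing undecided. A later test argued against it: Klk1b11, Klk15, Ifit1bl1, Ngp and F2rl2 allow a share of at most 1.74% (median), under the 10th percentile of 14.6%. The list also passed with the stromal score in the fit (camera adjusted p = 1.49e-33). Each group held 1 library rich in stromal transcripts, at 4200 (WT), 4304 (IFNa) and 4398 CPM (A20 KO) over the stromal list. The score could therefore take little from a group difference, and it holds Kdr, which itself rose with IFNa and in A20 KO. This test does not decide on stromal RNA. A response of the cells labelled A20 KO may be the source, a hypothesis that the design names and these data cannot separate from culture differences between mice or from IFNa given to these cultures too, which was not tested.

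Monocyte and macrophage markers were higher in A20 KO than in WT. The list passed with the stromal score in the fit (camera adjusted p = 4.3e-10). Since each group held 1 stromal-rich library and the score holds Kdr, this test does not decide on stromal RNA. A lower share of cDC2s that raised all other types alike would raise the cDC1 and monocyte lists together. Their median log2 fold changes were -1.15 and 1.76. The cDC1 list, however, holds genes abundant in the sorted WT cells, such as Id2 (849 ± 52.8 CPM) and Irf8 (807 ± 97.6 CPM). Its fall therefore does not measure how many other cells were sorted. Clec9a, less abundant in WT, fell from 20 ± 5.35 to 1.96 ± 0.919 CPM, and Xcr1 did not pass. The progenitor, basophil and T cell lists rose (medians 3.12, 1.93 and 1.6). The basophil and T cell calls were lost with an estimated correlation, at camera adjusted p = 0.068 and 0.094. This explanation was left undecided. Monocytes or macrophages among the sorted A20 KO cells and a change within cDC2s cannot be told apart: of 13 members with at least 10 CPM in both groups, 7 rose and 1 fell, and a sort for cDC2s could still pass cells that share their surface markers.

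Stromal transcripts differed between libraries of the same group. Lower depth is argued against: the library richest in them had the lowest total count of its group in 3 of 3 groups and yet held more stromal counts than the next library, 2.16-fold in WT, 1.53-fold with IFNa and 4.4-fold in A20 KO. Stromal cells or their RNA carried along in different amounts may account for it, but the test left this open. Over 8 genes, the median SD of the log2 ratio to Col1a1 was 0.534 of the SD of the gene itself, between the bounds set for either outcome. The SD of the ratio was small for Col1a2 (0.143 beside 1.4 for its level) and Sparc (0.282 beside 1.55). It exceeded that of the level for Dcn (1.06 beside 0.855) and Kdr (2.67 beside 2.05). Kdr also rose with IFNa and in A20 KO, so it is a poor measure of stromal material. No biological explanation was tested.

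Of the 10 splits of the 6 libraries of each comparison, 1, the real one, gave as many calls as the real groups, and 10 splits are too few for a share under 0.05. Each split was fitted on these 6 libraries only, unlike the fit of all 9 libraries that gave the results above. Each other split mixes libraries of both groups in its parts, so a group difference adds to the spread and keeps its gene calls low. It also keeps some of the group difference for the lists. The gap between the real and the other splits is therefore no support for the calls. The real groups gave 311, 1190 and 994 genes for IFNa vs WT, A20 KO vs WT and A20 KO vs IFNa, and the highest other split 0, 0 and 59. The fit of all 9 libraries gave 411, 1416 and 723. For gene lists the real groups gave 15, 20 and 15, and the highest other split 10, 17 and 11. The fit of all 9 libraries gave 14, 20 and 16 lists.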
